A study of Homo sapiens with 6 samples.

How the data were processed

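RNA-DNA hybrids were mapped in K562 cells, a human chronic myelogenous leukaemia line, by DRIPc-seq. In this assay genomic DNA cut with restriction enzymes is immunoprecipitated with the S9.6 antibody, which binds RNA-DNA hybrids, and the RNA part of the hybrids is sequenced with its strand. Cells had been transfected with 50 nM of a control siRNA pool (siC) or of a pool against BRG1 (siBRG1), the ATPase of the SWI/SNF chromatin remodelling complex, encoded by SMARCA4. Groups were taken from the labels: 1 siC and 2 siBRG1 DRIPc-seq libraries, and 1 siBRG1 total RNA-seq library. The remaining 2 of the 6 samples, siC DRIP-seq with and without RNase H, were not analysed here. The labels do not say whether the siBRG1 replicates came from separate cultures, so the spread between them may be technical.

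For DRIPc-seq the submitters' processing notes name Bowtie2, MACS2, bedtools and deepTools and the genome build hg38, with no versions or settings. Each library had 1 deposited list of broad peaks per strand, named W and C, and the replicates were not pooled. The deposited lists have no header line, so columns were read by their place in the MACS2 broad peak format, and the peak names carry a MACS2 label. The deposited score of a peak equals its −log10 q times 10, rounded down, in all but a few peaks (99.998% equal). Each deposited peak also has a fold enrichment (a ratio over background) and a −log10 p and −log10 q. The lowest deposited −log10 q was 1.00, so the lists hold peaks with a q-value up to 0.1. Fold and −log10 values are the authors' values for single peaks and served to describe, rank or filter peaks within a list, apart from 1 comparison of fold in the closing section and the highest −log10 q of mitochondrial peaks, which is printed for each library. Read depth behind the peak lists is not given in the sources used here. A peak list depends on depth, so covered length is not an amount of hybrid.

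The RNA library was deposited as RPKM for 19864 Ensembl genes. The submitters' processing notes name BWA, HISAT2, featureCounts, bedtools and deepTools for this kind of sample, without saying which tool served which step. Of the values above 0, 99.7% equalled a simple fraction within a relative tolerance of 1e-10, and the numerators of 82.9% of these were multiples of 5. Read as whole reads at that scale, those values sum to at least 17.8 M reads. A symbol was matched to 19773 genes and a RefSeq gene with coordinates to 19078. RNA of siC cells was not analysed here, so no RNA change and no check of the BRG1 knockdown can be given.

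Peaks on chromosomes 1 to 22 and X were merged within each library and strand. Lengths and overlaps were computed by base, strand by strand, with the Jaccard index (shared bases over the union) for pairs of libraries. Because 1 library stands against 2, no exact test could give a share below 1 of 3, and no p-value is printed. Instead each of the 3 libraries was treated in turn as the odd one, and the values for siC were set beside those for each siBRG1 library. Whole peaks were also compared, counting a peak as shared at an overlap of 1 bp.

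Gene positions came from the RefSeq table for GRCh38.p14, the patch release of the build the peaks use, with 38151 protein-coding and lncRNA genes. That table has no strand and no exons. The hybrid strand of a gene was therefore the strand with more covered bases over the 3 libraries, and W was read as plus and C as minus from 24 genes whose direction of transcription is textbook knowledge. Coverage of a gene is the percent of its bases, outside any other protein-coding or lncRNA gene, that lie under peaks on its hybrid strand. Genes with at least 2 kb of such sequence (28187) entered the gene comparison, and 0.3 kb sufficed for gene lists, a limit set after gene lengths and before coverage was seen. A gene stood apart in a library when its coverage differed from both others by 20 percentage points or more in 1 direction. Promoters (1 kb either side of the start), gene bodies and 5 kb downstream were defined for 11475 genes whose covered bases were at least 90% on 1 strand and 500 bp or more. These steps replace a planned use of annotated strand. A share of the genome per region was not computed, since no genome was used.

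Named genes followed a rule set before the data were examined. Among genes of 5 kb or more with an RPKM of 1 or more that moved from siC in the same direction in both siBRG1 libraries, it takes the 10 with the largest gain and the 10 with the largest loss of coverage, ranked by the smaller of the 2 differences in percentage points, and 5 each way in covered kb. From each of 17 gene lists it takes the 2 members with the largest gain and the 2 with the largest loss, and it adds SMARCA4 and the 5 longest intervals covered in both siBRG1 libraries and not siC, and in siC alone. NEAT1 and MALAT1 were added after their values were seen. A gene that the rule takes is not reported here. Each list's median change was placed among 10000 random lists of the same size matched on RPKM and gene length in 8 by 8 bins. A list outside the central 95% (percentile below 2.5 or above 97.5) was counted as standing apart, a limit set at analysis and not corrected for 17 lists. Coverage was correlated with log2(RPKM + 1) across genes, which are not independent replicates. Intervals on shares of genes are exact binomial 95% intervals and cover counting error only.

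Scripts were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Interval arithmetic was tested on simulated data against base-by-base bitmaps, with 0 differing values. The gene rule was tested on 28187 simulated genes with the spread of the siBRG1 replicates and 200 planted changes of 30 points. It recovered 87% of planted gains and 80% of planted losses, and called 24 gains and 47 losses among unplanted genes. Changes were planted only in genes with siC coverage of 30% or more. Median siC coverage was 6.23% among genes with a peak in any library, so the recovered shares do not hold for most genes. Of 100 random lists of 25 genes drawn from 17729, 6 stood apart with no shift and 100 did after a shift of 3 points down.

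Alternatives, set before the data were examined, were a stricter peak limit (the upper 50% of each list by −log10 q), an equal number of peaks per list of a strand, gaps up to 1 kb bridged, peaks under 500 bp left out, strands merged, every sequence in the files, each siBRG1 replicate left out, other overlaps, thresholds of 10 and 40 points, gene bodies with 5 kb downstream, filters on RPKM and length, another pseudocount, and matching on siC coverage. Genes that overlap no other gene were added after seeing the data. Mitochondrial peaks entered only the alternative with every sequence. The upper 50% limit was each list's own median −log10 q. On the W strand it was 5.33 in siC and 4.68 and 4.44 in siBRG1 replicates 1 and 2. On the C strand it was 5.72, 4.98 and 4.77. The limit was thus stricter for siC, which can shrink or reverse a loss in siBRG1.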

Results

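RNA-DNA hybrids were compared between control K562 cells (siC) and cells given siRNA against BRG1, a SWI/SNF ATPase (siBRG1), to ask where hybrid peaks differ between them. The data were strand-specific peak lists from 1 siC and 2 siBRG1 DRIPc-seq libraries, with an RPKM table from 1 siBRG1 RNA library. The number of reads behind each peak list is unknown, and siC had no replicate, so the gap between the siBRG1 libraries is the only measure of spread. All coordinates are hg38.

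SMARCA4, the gene that encodes BRG1 (chromosome 19, 10961030 to 11062273), was covered by hybrid peaks over 10.9% of its length in siC and over 9.56% and 8.57% in siBRG1 replicates 1 and 2. The mean difference of −1.83 points was −0.997 with equal numbers of peaks, −0.202 among the upper 50% of each list by −log10 q and −2.89 with gaps up to 1 kb bridged. Its RPKM in the siBRG1 RNA library was 6.46. RNA of siC cells was not analysed here, so the knockdown itself was not checked.

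The strand of each list was read from 24 genes of known direction. In each library, W peaks lay on the plus-strand genes and C peaks on the minus-strand genes for 24 of 24, so W was taken as plus and C as minus, which is an assignment and no separate test. Among 17631 genes of 2 kb or more that overlap no other gene, those for which the other libraries set a strand were used. Of their covered bases, 97.0% in siC, and 97.9% and 98.0% in the siBRG1 libraries, lay on that strand. Genes with a peak in the tested library alone were thus left out.

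Hybrid peaks covered less of the genome in both siBRG1 libraries than in siC. The siC list held 150686 peaks, and the siBRG1 lists held 117630 ± 677 (SD, n = 2), which is 21.9% fewer. Peaks covered 68.4 Mb in siC and 52.9 ± 1.53 Mb (SD, n = 2) in siBRG1, 22.6% less. Median peak length differed by less than the replicates did, at 258 bp in siC and 263 and 256 bp in siBRG1. The shortfall was seen on each chromosome, with siBRG1 to siC ratios from 0.695 on chromosome X and 0.715 on chromosome 13 to 0.821 on chromosome 16. When every list of a strand was limited to the same number of its strongest peaks, the ratio of covered length was 0.933.

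Much of the hybrid map was common to the 3 libraries, and siC alone held the largest private part. Bases covered in all 3 came to 34.7 Mb, 50.7% of the siC coverage and 64.2% and 66.9% of the siBRG1 coverage. A further 18.7 Mb was covered in siC alone, against 7.13 Mb and 7.55 Mb in siBRG1 replicate 1 or 2 alone. In the opposite direction, 3.37 Mb was covered in both siBRG1 libraries and not in siC, less than the 6.22 Mb missing only from replicate 1 and the 8.81 Mb missing only from replicate 2. Counted as whole peaks, 37370 siC peaks (24.8%) met no siBRG1 peak, while 12191 (10.3%) and 13806 (11.8%) peaks of the siBRG1 libraries met none in the other lists. The siBRG1 libraries were scarcely more alike than siC and replicate 1, with Jaccard indices of 0.562 between the siBRG1 libraries, 0.552 for siC with replicate 1 and 0.516 for siC with replicate 2. With equal numbers of peaks the siC pairs were on average 0.00827 more alike than the siBRG1 pair.

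**Figure D1:**
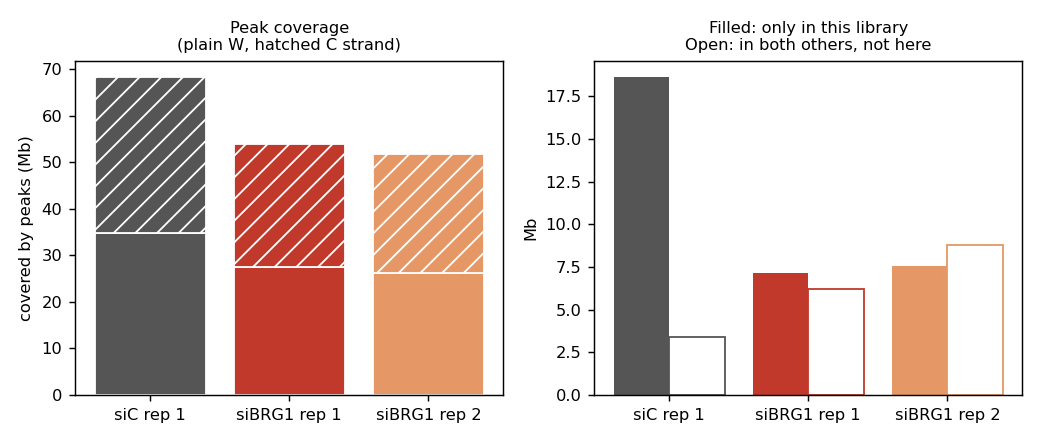
Left, Mb covered by peaks in each library, plain for the W and hatched for the C strand, with 68.4 Mb in siC and 54.0 and 51.8 Mb in the siBRG1 libraries. Right, Mb covered in 1 library alone (filled) and in both others but not in it (open), where siC has 18.7 and 3.37 Mb.

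The longest intervals that separated the groups lay in few named genes. Of the 5 longest covered in both siBRG1 libraries and not in siC, 3 were in genes: 1565 bp in CCDC8 (chromosome 19, 46411351 to 46412915), 1424 bp in EPPK1 (chromosome 8, 143868523 to 143869946) and 1343 bp in TYK2 (chromosome 19, 10352898 to 10354240), which encodes a Janus kinase. The other intervals, of 1634 bp (chromosome 16, 18385696 to 18387329) and 1338 bp (chromosome 7, 84777532 to 84778869), lay in no protein-coding or lncRNA gene. Among the 5 longest in siC alone were 2497 bp in HERC2, a ubiquitin ligase gene (chromosome 15, 28155580 to 28158076), and 2235 bp in OPA1, whose product fuses mitochondrial inner membranes (chromosome 3, 193694769 to 193697003). The longest, 3039 bp on the C strand (chromosome 7, 64976434 to 64979472), lay within the overlapping genes ZNF117 and ERV3-1-ZNF117, and 2250 bp on the W strand (chromosome 22, 24372004 to 24374253) within the overlapping genes SPECC1L and SPECC1L-ADORA2A. The hybrid strand of these overlapping genes was not resolved. The remaining siC interval, 2553 bp on chromosome 17 (38686326 to 38688878), lay in no such gene.

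Gene bodies held most of the hybrid coverage, and the shortfall in siBRG1 was smallest at gene starts. Gene bodies took 70.7% of covered bases in siC and 73.7% and 73.5% in siBRG1, and sequence outside genes took 14.4% against 12.3% and 12.2%. With the upper 50% of each list by −log10 q, the gain in gene body share was 0.683 points in place of 2.95. Peaks covered 5.55% of promoter sequence in siC and 5.43% and 6.02% in siBRG1, a difference smaller than that between the replicates. Gene body coverage was 6.09% in siC and 5.02% and 4.81% in siBRG1, and coverage of the 5 kb downstream of genes was 2.99% against 2.21% and 2.33%. Along 3645 expressed genes of 10 kb or more, the first of 20 bins was covered over 9.57% in siC and 9.23% and 9.99% in siBRG1, and the last bin over 16.3% against 13.1% and 11.5%.

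**Figure D2:**
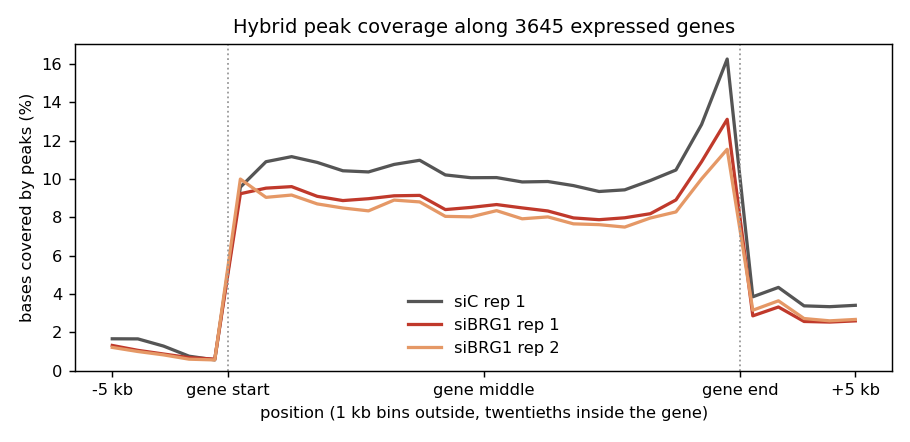
Percent of bases covered by peaks along 3645 expressed genes, in 1 kb bins for 5 kb on either side and in 20 equal bins inside the gene, with 1 line per library. The siBRG1 lines lie on either side of the siC line in the first bin inside the gene and below it in the other bins inside the gene, with 16.3% in siC against 13.1% and 11.5% in the last bin.

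At single genes, coverage was lower in both siBRG1 libraries than in siC for 9776 of 28187 genes and higher in both for 1657. Only 14941 of the 28187 had a peak in any library, and the others could not differ. For comparison, replicate 1 lay above both other libraries in 2680 genes and below both in 4730, and replicate 2 lay above in 2435 and below in 6509. By 20 percentage points or more, siC stood above both siBRG1 libraries in 66 genes (46 protein-coding and 20 lncRNA) and below them in 13. Replicate 1 stood above in 28 and below in 6, and replicate 2 above in 21 and below in 48. With equal numbers of peaks siC stood above in 32 genes and below in 31. Unplanted genes in the simulation, which carried only the spread between replicates, gave 47 and 24, so these counts do not mark single genes as changed.

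Among genes of 5 kb or more with an RPKM of 1 or more, the gain of coverage that ranked first was at NOP56, which encodes a core protein of box C/D snoRNPs and hosts snoRNAs (chromosome 20, 2652632 to 2658393), with 9.35% in siC and 31.1% ± 0.871 (SD, n = 2) in siBRG1. Shorter genes, left out of this ranking, had larger differences, as at RPL36. TRMT2A, a tRNA methyltransferase gene, went from 40.6% to 60.1% ± 1.25, but the difference was −11.6 points when gaps up to 1 kb were bridged. RAD9A, part of the checkpoint clamp that senses DNA damage (chromosome 11, 67391986 to 67398412), and ARHGEF39 had no peak in siC and 17.02% ± 2.41 and 18.1% ± 3.55 in siBRG1. TRAPPC2L was covered over 7.33% and 22.9%, ICAM5 over 20.6% and 37.0%, and ARFGAP2 over 20.7% and 34.3%. PNPLA2, which encodes adipose triglyceride lipase, at 12.2% and 26.7%, and ZNHIT1, at 7.62% and 21.5%, changed sign among the upper 50% of peaks, to −4.14 and −0.730 points. Under that limit the NOP56 difference was 0.0607 points in place of 21.7, those of RAD9A, ARHGEF39 and TRAPPC2L were 0, and that of ICAM5 was 4.04 in place of 16.4, while ARFGAP2 stayed at 13.7 and TRMT2A was at 34.8. RAD9A was at 5.37 points without peaks under 500 bp. With gaps bridged the differences were larger at NOP56 (36.5), ICAM5 (30.8) and ZNHIT1 (29.7). By the same limits the 5 largest gains in covered kb were at NBEAL2 (2.07 to 5.29 kb), HDAC4, a histone deacetylase gene (4.81 to 7.75 kb), TXNRD2, PFKL and AGRN (2.98 to 6.04 kb). In percentage points these were 11.6, 0.857, 4.52, 8.89 and 8.499, and among the upper 50% of peaks 1.22, 0.161, 1.58, 5.70 and 0.990. With gaps bridged AGRN differed by 13.6 points, and with equal numbers of peaks HDAC4 by 1.29.

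Within the same limits on length and RPKM, the loss of coverage that ranked first was at MAT2A, which encodes the S-adenosylmethionine synthase of most tissues (chromosome 2, 85539168 to 85545281), with 57.3% in siC and 13.98% ± 5.35 (SD, n = 2) in siBRG1. Among the upper 50% of peaks the MAT2A difference was 0.883 points in the other direction, and the same held for SHARPIN (56.3% and 28.7%; 3.19 points) and EIF4G2 (42.1% and 18.6%; 9.25 points). That limit lies at a higher −log10 q in siC than in siBRG1, so it removes siC peaks of a strength kept in siBRG1. DDX5, an RNA helicase gene (chromosome 17, 64498254 to 64506866), went from 40.6% to 14.2% ± 1.54, ICAM1 from 62.6% to 35.9% ± 0.0602 of the 2350 bp that lie outside other genes, and ATP5F1B, a subunit gene of mitochondrial ATP synthase, from 63.1% to 39.6% ± 3.63. THYN1 had 22.2% in siC and no peak in either siBRG1 library, but its difference was 0 with equal numbers of peaks and among the upper 50%. ECM1 (28.96% and 4.55%), IRF2BP2 (31.7% and 10.1%) and SBDS, a ribosome maturation factor gene (37.7% and 11.5%), complete the 10. SBDS differed by −26.2 points, and by −16.5 with equal numbers of peaks and −8.25 among the upper 50%. With equal numbers EIF4G2 differed by −10.3 in place of −23.5 points, and SHARPIN by 8.29 in the other direction. In kb the 5 largest losses were in long genes: MACF1, a cytoskeletal linker gene (59.0 kb in siC, 45.1 and 45.2 kb in siBRG1), ADK, WDR70, ERC1 and VPS13B (60.3 to 49.0 kb). Their differences in points were −3.46, −2.60, −3.25, −2.55 and −1.37, with equal numbers of peaks −2.01, −1.76, −1.75, −1.21 and −0.624, and among the upper 50% −1.96, −1.45, −0.901, −2.11 and −1.24. With gaps bridged all 5 were larger, as at MACF1 (−5.19).

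**Figure D3:**
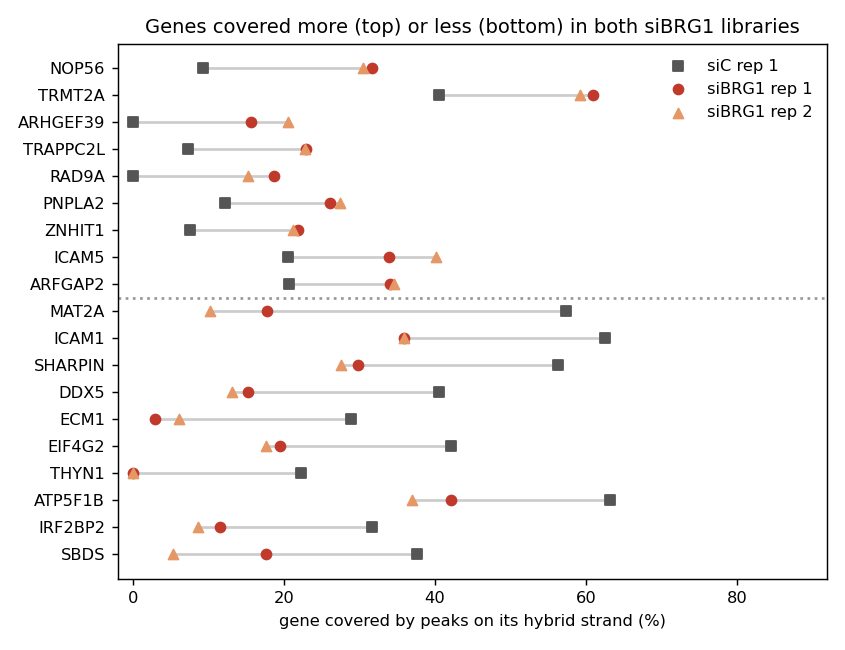
Percent of each gene covered by peaks on its hybrid strand in siC (squares), siBRG1 replicate 1 (circles) and replicate 2 (triangles), for 9 of the genes of 5 kb or more and RPKM of 1 or more with the largest gain (top) and the 10 with the largest loss (bottom). MAT2A lies at 57.3% in siC and 17.8% and 10.2% in siBRG1, and NOP56 at 9.35%, 31.7% and 30.5%.

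From siC to siBRG1, the median coverage change of spliceosome, heat-shock and SWI/SNF genes was further below 0 than in matched random lists, and these were the 3 of 17 lists that stood apart. The hepatocyte, neuron and T cell lists among the 17 had few members with a peak and could hardly stand apart. For scale, of the 14941 genes in the gene comparison with a peak in any library, 9776 were lower in both siBRG1 libraries and 1657 higher. Of 31 core spliceosome genes 21 were lower in both siBRG1 libraries and 6 higher, which is no clear excess of losses over that scale. The list stood apart by the size of its median change, −4.96 points (percentile 0.01), which was −2.42 (percentile 1.43) among the upper 50% of peaks. SRSF2, a splicing factor gene, went from 30.4% to 18.9%, and SNRPD3, of the Sm ring, from 18.6% to 9.59%. SRSF2 differed by −0.437 points without peaks under 500 bp, and SNRPD3 by −0.0708 among the upper 50% and −14.2 with gaps bridged, in place of −9.03. SNRPB (15.9% and 20.4%) and SNRPG (21.6% and 23.6%) were higher, but changed sign when gaps were bridged (SNRPB, −4.42 points, against 12.99 among the upper 50% of peaks) or among the upper 50% (SNRPG, −6.81 points). Of 14 heat-shock genes 12 were lower and 0 higher, with a median change of −5.56 points (percentile 0.24), as at HSP90AB1 (34.7% and 15.3%) and HSPA8 (61.5% and 45.7%). With gaps bridged these differed by −30.3 and −29.6 points in place of −19.5 and −15.8. HSPA1A and HSPA1B are near-identical, so their coverage is uncertain. Of 26 SWI/SNF subunit genes 20 were lower and 2 higher, with a median change of −2.37 points (percentile 0.22). Among them DPF2 went from 19.3% to 10.8% and BCL7A from 12.7% to 7.02%, while BRD9 went from 4.76% to 8.14%, and PHF10 stood at 3.66% in siC and 3.84% and 3.68% in siBRG1, with a difference of −1.27 points among the upper 50% of peaks and 1.42 without peaks under 500 bp. The SWI/SNF percentile was 5.14 among the upper 50% of peaks and 13.3 with equal numbers of peaks, inside the central range, with median changes of −1.17 and −0.449 points, and BCL7A differed by −2.10 and −2.98 points in place of −5.67.

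Genes for hybrid removal and genome maintenance did not stand apart from matched genes. Of 19 genes for R-loop nucleases and helicases 15 were lower and 0 higher (median −1.996 points, −0.591 with equal numbers of peaks; percentile 17.6), led by DDX5 and by PIF1 (17.2% and 8.93%). In the THO/TREX export list 8 of 13 were lower and 1 was higher (percentile 59.5), namely DDX39A (27.5% and 36.3%), while THOC5 went from 14.9% to 9.66% and SARNP from 24.55% to 21.5%. The PIF1 difference of −8.24 points was −15.2 among the upper 50% of peaks and −3.22 with gaps bridged, and the SARNP difference of −3.06 was −1.61 and −10.9. DDX39A differed by 0.0189 points among the upper 50% and by 15.5 with gaps bridged, in place of 8.80. The Fanconi and recombination list had 12 of 18 lower and 2 higher (percentile 13.5, and 0.98 without siBRG1 replicate 2). FANCD2 went from 24.8% to 19.3% and UBE2T from 10.1% to 4.22%. With equal numbers of peaks they differed by −2.66 and −3.12 points in place of −5.53 and −5.86, and UBE2T by 0 without peaks under 500 bp. FANCG stood at 7.90% in siC and 8.09% and 8.60% in siBRG1, a difference that was 0 without peaks under 500 bp. FANCF stood at 13.04% and 14.98%, and its difference of 1.94 points was −0.319 among the upper 50% of peaks, 6.90 with equal numbers of peaks and 7.76 without peaks under 500 bp. Of 38 replication genes 23 were lower and 6 higher (percentile 75.3). RFC2 stood at 27.7% and 21.9% and GINS3 at 13.3% and 5.25%. CDC45 stood at 15.03% in siC and 17.02% and 19.1% in siBRG1, and PRIM1 at 5.63% against 10.98% and 7.38%. GINS3 was 1.56 points higher with equal numbers of peaks. Among the upper 50% of peaks the differences were −2.12 points at PRIM1, −0.0621 at GINS3 and 1.12 at CDC45, which was at 5.10 with gaps bridged. Among 24 common fragile site genes, long genes prone to breakage under replication stress, 22 were lower (percentile 55.2), such as WWOX (54.7 and 44.0 kb) and PARD3 (28.9 and 17.9 kb), and 1 was higher, MAD1L1 (16.5 kb in siC, 16.6 and 19.96 kb in siBRG1). In points WWOX and PARD3 differed by −1.02 and −1.55, with equal numbers of peaks by −0.279 and −0.768, and among the upper 50% by −0.766 and −0.503. MAD1L1 differed by 0.0213 and 0.883 points in the siBRG1 libraries, and on average by 1.74 with equal numbers of peaks and 0.0622 without peaks under 500 bp.

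Ribosomal protein, snoRNA host, histone, erythroid and stress lists had members that went both ways. Ribosomal protein genes had 40 of 71 lower and 12 higher (percentile 61.8). RPLP2 went from 16.4% to 44.1% and RPL36 from 44.6% to 89.7%, though the RPL36 difference of 45.1 points was −2.21 with gaps bridged and 89.7 without peaks under 500 bp, while RPL10 went from 59.4% to 17.4% and RPS27 from 38.0% to no peak. The 7 measured snoRNA hosts with an RPKM had 5 lower and 1 higher, which was NOP56 (percentile 16.95), and among hosts with no RPKM, SNHG19 had 78.2% in siC and no peak in siBRG1 and SNHG8 went from 76.6% to 22.8%. The differences of RPS27 and SNHG19 were 0 with equal numbers of peaks and among the upper 50%. Histone genes had 27 of 46 lower and 2 higher (percentile 29.03). H2AC20 stood at 69.8% and 81.8% and H3C10 at 66.3% in siC and 66.7% and 72.4% in siBRG1, against H3C7 at 92.3% in siC and 71.1% and 35.0% in siBRG1 and H4C12 at 64.1% and no peak. The H3C7 difference of −39.3 points was 0 among the upper 50% of peaks and −92.3 without peaks under 500 bp, and those of H2AC20, H3C10 and H4C12 were 0 without peaks under 500 bp. Ribosomal protein and histone genes have close copies, so their values are uncertain. In the erythroid list 14 of 25 were lower and 5 higher (percentile 70.8). The erythroid regulators NFE2 (15.07% and 23.02%) and GATA1 (19.65% in siC, 21.4% and 25.9% in siBRG1) were higher, and the globin genes HBA2 (86.0% and 65.2%) and HBZ (28.7% and 11.3%) were lower. GATA1 differed by 1.76 and 6.23 points in the siBRG1 libraries, and on average by 9.67 with gaps bridged and 8.25 without peaks under 500 bp. HBZ had −28.7 points without peaks under 500 bp. In the immediate-early and stress list 9 of 24 were lower and 5 higher (percentile 35.3). ATF4 stood at 58.3% and 79.6% and GADD45B at 6.99% and 26.8%, against EGR1 at 45.3% and 34.3% and IER2 at 53.2% in siC and 44.1% and 29.1% in siBRG1. GADD45B differed by 0 among the upper 50% of peaks and without peaks under 500 bp, and IER2 by −4.73 in place of −16.6 points with equal numbers of peaks and among the upper 50%, and by −28.9 with gaps bridged. In the next lists no member was higher in both siBRG1 libraries. Of 10 loci often used for R-loop PCR 8 were lower and 0 higher (percentile 10.4), among them EGR1 and TFPT (16.8% and 8.66%). TFPT had an RPKM of 0 and was measured on the W strand, set by its peak bases alone. Its coverage may therefore be antisense or come from a neighbouring transcript. Genes of other cell types were nearly bare of peaks: 14 of 15 hepatocyte, 10 of 15 neuron and 9 of 13 T cell genes had none in any library (percentiles 50.0, 54.6 and 50.5). With most members bare, the median change was 0 in each of these lists. Their percentiles therefore lay near 50 by construction and test nothing. The few named members with peaks were TF (1.36% and 0.961%), SYN1 (1.84%), SYT1 (0.0427%) and CD247 (0.248%), the last 3 in siC alone, and CD5 (1.59% and 0.239%; 0.239 points higher with equal numbers of peaks). Coverage was taken on the strand with more peak bases, which was C at SYT1 and CD5. No annotated strand was used, so peaks of such genes may lie antisense to them. All 5 differed by 0 among the upper 50% of peaks, and with gaps bridged SYN1 differed by −3.44 points and TF by −0.0746.

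**Figure D4:**
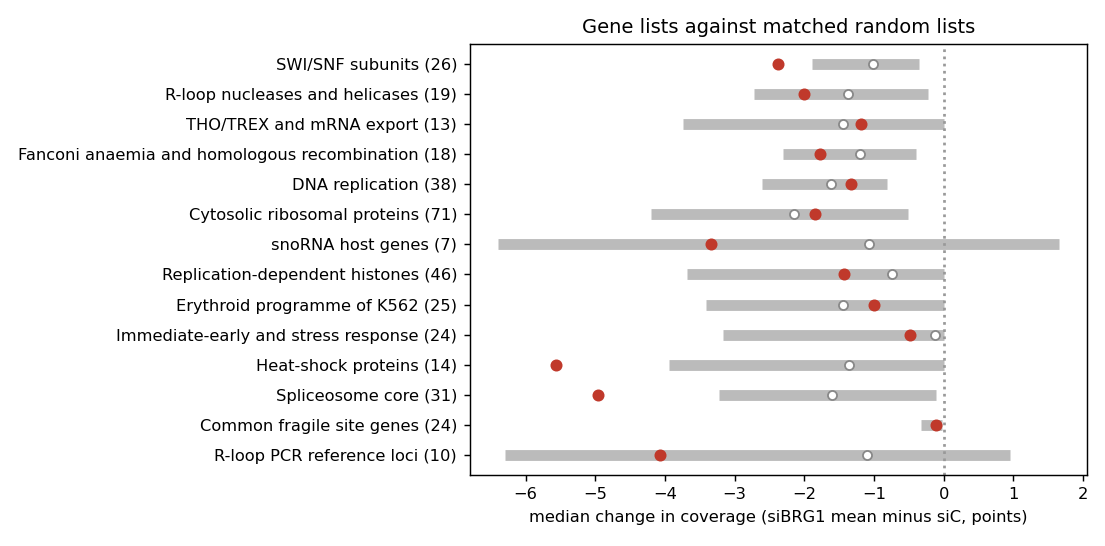
Median change in gene coverage, siBRG1 mean minus siC in percentage points, for 14 gene lists (red points, with the number of members), beside the median (open points) and central 95% (grey bars) of 10000 matched random lists. Spliceosome (−4.96), heat-shock (−5.56) and SWI/SNF (−2.37) lists lie below their bars.

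Genes with more RNA in siBRG1 cells had more hybrid coverage in all 3 libraries. Across 17729 genes, coverage rank-correlated with log2(RPKM + 1) at a Spearman rho of 0.780 in siC and 0.771 and 0.765 in siBRG1, with a Pearson r of 0.617, 0.585 and 0.574. Among genes with an RPKM of 1 or more the mean rho of the siBRG1 libraries was 0.422. A hybrid peak was present in 15.05% (exact 95% interval 13.9 to 16.3) of the 3396 genes listed at an RPKM of 0 in siC, and in 9.57% (8.60 to 10.6) and 8.69% (7.76 to 9.68) in siBRG1. At an RPKM of 10 to 100 the shares were 99.0%, 97.7% and 96.9% of 2937 genes. Mean coverage in siBRG1 relative to siC was 0.781 and 0.744 at an RPKM of 0, and 0.917 and 0.853 at 100 or more. ASNS, the asparagine synthetase gene, named after its value was seen, had an RPKM of 170 and no peak in any library, but only 440 bp of it lies outside other genes.

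**Figure D5:**
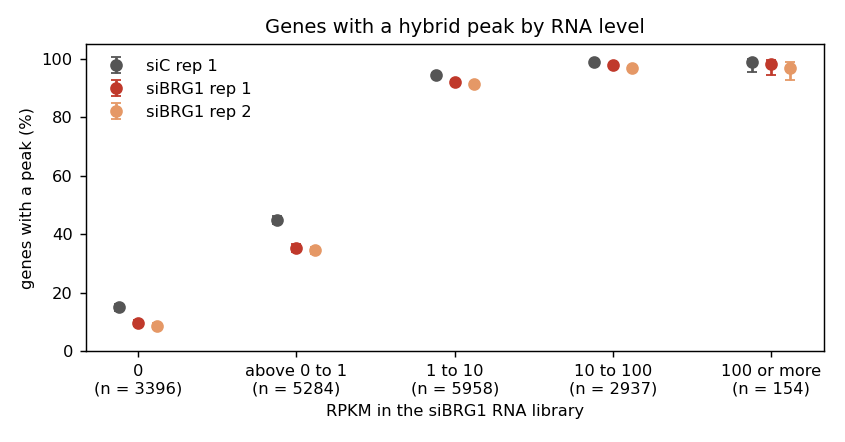
Percent of genes with a hybrid peak by RPKM class in the siBRG1 RNA library, for each DRIPc-seq library, with exact binomial 95% intervals that cover counting error only. Shares climb from 15.05%, 9.57% and 8.69% at an RPKM of 0 to 99.0%, 97.7% and 96.9% at 10 to 100.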

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

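Peaks on the mitochondrial genome entered only the alternative that takes every sequence in the files, and are given here as values, with no test chosen. They were present in each DRIPc-seq list, above the limit that a count of 0 allows: 7 in siC, 8 in siBRG1 replicate 1 and 9 in siBRG1 replicate 2. On the W strand they covered 9.91 kb in siC and 10.1 and 8.95 kb in siBRG1, and on the C strand 6.51 kb against 5.92 and 6.22 kb. The highest −log10 q of these peaks was 1993 in siC and 1077 and 383 in siBRG1.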

How the results depend on the processing

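Of these settings, the comparison limited to genes that overlap no other gene was chosen after seeing the data. No paired analysis was possible because siC and siBRG1 share only replicate number 1. With 1 siC library, every value rests on that library, and leaving out a siBRG1 replicate leaves 1 against 1; for the sharing between siBRG1 replicates this gives no value. Read depth behind the lists is unknown, which limits every count. Under the alternatives, 128 values of the main results stayed within their limits, 41 moved in size, 1 changed direction, 2 no longer stood apart and 1 newly did. For single genes 466 stayed, 174 moved in size, in several cases to 0, and 16 changed direction.

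Covered length stayed lower in siBRG1 under every alternative run. With equal numbers of peaks, the ratio of covered length was 0.933 and that of peak number 1.00, by construction, and the siC pairs became more alike than the siBRG1 pair by 0.00827 in Jaccard index (−0.0278 as deposited). Genes standing apart were then 32 above and 31 below in siC, and the SWI/SNF percentile was 13.3. The ratio of peak number was 0.794 with gaps bridged, 0.786 without peaks under 500 bp and 0.787 with strands merged.

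Intervals covered in both siBRG1 libraries and not siC, and in siC alone, numbered 19767 and 63356 among the upper 50% of peaks, and 12816 and 43976 without peaks under 500 bp, since fewer peaks entered. As whole peaks they numbered 5763 and 37370 at an overlap of 1 bp, and 7301 and 47063 at 0.5 of the peak. Without 1 siBRG1 replicate the first count ranged from 88318 to 91770 and the second from 156001 to 161713.

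Genes above and below in siC numbered 155 and 34 with gaps bridged, 309 and 68 at 10 points, 5 and 1 at 40 points, 0 and 1 with 5 kb downstream added, where the added length dilutes each change, and 1432 and 141 for any peak against none. Genes above numbered 39 at an RPKM of 1 or more and 43 among genes overlapping no other. Genes below numbered 27 without peaks under 500 bp. Without 1 siBRG1 replicate they ranged from 98 to 152 above and from 45 to 54 below.

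The SWI/SNF percentile was 5.14 among the upper 50% of peaks, and the Fanconi percentile ranged from 0.98 to 17.96 without 1 replicate. Heat-shock and spliceosome lists stayed below 2.5 under every alternative run for gene lists. Gene lists were not run with gaps bridged or without peaks under 500 bp. The share of bases on the hybrid strand was 98.8% among the upper 50% of peaks, where the gain in gene body share was 0.683 points (2.80 with promoters of 2 kb either side). The mean Spearman rho was 0.422 and Pearson r 0.419 at an RPKM of 1 or more, rho 0.762 and r 0.597 for genes of 2 kb or more, and r 0.558 with a pseudocount of 0.1.

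Differences that changed direction, in points, were PNPLA2 −4.14, ZNHIT1 −0.730, MAT2A 0.883, SHARPIN 3.19, EIF4G2 9.25, PHF10 −1.27, FANCF −0.319, PRIM1 −2.12 and SNRPG −6.81 among the upper 50% of peaks. They were SHARPIN 8.29, GINS3 1.56 and CD5 0.239 with equal numbers of peaks, TRMT2A −11.6, RPL36 −2.21 and SNRPB −4.42 with gaps bridged, and SNRPG −0.485 without peaks under 500 bp. Except where construction is named, the cause was not tested.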

Other observations

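The tests of fold at matched p, of promoter to gene body coverage and of the detained-intron list, the comparison of missed peaks with those between siBRG1 replicates, and the lncRNAs named here, were chosen after results were seen. The detained-intron list was composed after the named genes' values were seen, among them that of its member SRSF2, and before its median. Its members SRSF2, SRSF3 and SRSF7 also belong to the core spliceosome list, so the lists are not independent. The comparison of its percentiles with the gap between replicates was added after they were seen.

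Among genes with an RPKM of 1 or more, those under 20 kb had higher siBRG1 to siC ratios of mean coverage than longer ones in each siBRG1 library. For genes under 5 kb, of 5 to 20 kb, of 20 to 100 kb and over 100 kb, the ratios were 0.925, 0.891, 0.846 and 0.829 in replicate 1 and 0.840, 0.846, 0.806 and 0.801 in replicate 2. For genes under 5 kb the replicates differed by more than the averaged ratios did across classes (0.883 to 0.815). By chromosome the ratio was lowest on X (0.695), 13 (0.715) and 14 (0.743), and highest on 16 (0.821), 22 (0.815) and 21 (0.813). The nuclear lncRNA MALAT1 (chromosome 11, 65497738 to 65506516) was covered over 58.2% in siC and 45.0% and 16.1% in siBRG1 (SD 20.4, n = 2), so the replicates lay farther apart than siC and replicate 1. Its neighbour NEAT1, the scaffold RNA of paraspeckles, was covered over 37.5%, 33.5% and 32.04%. With gaps up to 1 kb bridged, the differences of MALAT1 and NEAT1 were −39.6 and −10.2 points in place of −27.6 and −4.74. Of the bases covered in both siBRG1 libraries and not siC, 5.47% lay at promoters. The share was 1.56% for siC alone, 2.88% for replicate 1 alone and 4.72% for replicate 2 alone. For bases in siC and replicate 1 only, and in siC and replicate 2 only, it was 1.62% and 2.05%. The 5.47% is over 40411 intervals with a median of 19 bp, against 5763 whole peaks, so many are parts of longer peaks.

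If the shortfall of 21.9% of peaks in siBRG1 were a loss of whole peaks independent of their strength, strong siC peaks would be missed about as often as weak ones. Of the strongest of 10 equal bins of siC peaks, 0.597% and 1.33% met no peak of siBRG1 replicate 1 or 2, beside 0.669% and 0.572% missed between the replicates. Neither replicate met 0.405% of the strongest siC bin, against 71.4% of the weakest. Between the replicates, 63.4% and 61.1% of the weakest bin were missed too, so the contrast of weak and strong peaks decides nothing by itself. The low share missed in the strongest bin, beside a shortfall of 21.9%, argues against such a loss. If fewer reads lay behind the siBRG1 lists, peaks of the same −log10 p would need a higher fold, and they had one on both strands and in all 3 ranges tested. The smallest difference was 0.0120 (replicate gap 0.00177), and at −log10 p of 18 to 22 on the W strand the median fold was 7.19 in siC and 7.77 and 8.002 in siBRG1. Lower depth may therefore contribute to the shortfall, by an amount that was not measured, and a lower local background would act on fold the same way. A loss in proportion at every locus, which would take weak peaks first, and an effect of siBRG1 on hybrids stay open, untested with 1 siC library.

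Coverage of promoters relative to gene bodies was 0.911 in siC and 1.08 and 1.25 in siBRG1. If libraries of 1 group vary this much among themselves, the replicates should differ by a large part of the gap from siC to the nearer of them. They differed by 0.172, against a gap of 0.170 from siC to replicate 1, so variation between libraries may account for the shift. An effect of siBRG1 on promoter hybrids stays open, and GC content was not tested because no genome was used.

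Lower coverage of MAT2A, DDX5, EIF4G2 and MALAT1, of which MALAT1 is a nuclear RNA and MAT2A RNA can be held in the nucleus by a detained intron, raised the hypothesis that nuclear-retained RNA was carried into the siC library. A list of 25 measured detained-intron and splicing-factor genes, without MAT2A and DDX5, should then lie below percentile 2.5 in both siBRG1 libraries. Its percentile was 10.3 for replicate 1 (10.25 before rounding) and 2.14 for replicate 2. The requirement was therefore not met in replicate 1. With replicate 2 below the limit, the miss was bound to be smaller than the replicate gap, which therefore decides nothing. For the siBRG1 mean, the measure used for the other lists, the percentile was 2.35 with a median change of −3.51 points, with 17 of 25 lower in both and 2 higher. The prediction therefore failed as stated, while the siBRG1 mean lay below the limit. The explanation is neither borne out nor excluded, and a biological difference was not tested.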
